A study of Halobacterium salinarum NRC-1 with 8 samples.

How the data were processed

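RNA from Halobacterium salinarum NRC-1 was measured on 2-colour genome tiling arrays. The 8 samples came from 2 strains, each taken once in mid-log, late-log, early stationary and late stationary phase. The strain called wild type in the labels lacks ura3, and D2099 lacks VNG2099C as well. Both were grown at 37 °C with added uracil, per the labels' protocols. Every sample was hybridised against a common NRC-1 reference RNA on 2 arrays with the dyes exchanged, which made 16 arrays. The 2 arrays of a sample held the same extracts and were counted as 1 replicate.

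The deposited scanner files held spot intensities in the green and red channels, with no normalization, as read by Agilent Feature Extraction 10.7.3.1, per the file headers. They also held a log10 ratio of red over green processed signals, background-subtracted and dye-normalized by that software, per the file headers. The authors' deposited matrix held 1 log10 ratio per probe and sample, of sample over reference and averaged over the dye exchange, per the labels. The method behind its normalization is not given in the sources used here. The medians of its 8 columns were -0.0007, 0.001, 0.1067 and 0.0547 in the wild type and -0.0004, 0.0796, 0.2126 and 0.1294 in D2099, in the order of the phases, so its centring stayed unknown. Across genes its columns correlated with the ratios computed here at r = 0.97 to 0.994, which also bore out the direction of the ratios taken from the dyes in the file names. Arrays of the same dye orientation correlated over all probes at r = 0.055 to 0.904.

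Mean spot signals were corrected with normexp (offset 50) on the background medians, and log2 ratios were normalized within each array by loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Each ratio was turned to sample over reference, and the 2 arrays were averaged. Control spots and spots marked as outliers by the scanner software were left out. Each array had 61657 probe spots, of which 88.0% to 95.2% were well above background in at least 1 channel and 0 were saturated. The number of arrays limits the precision. Median red signals lay between 266 and 493 on the D2099 arrays and between 719 and 1048 on the wild type arrays.

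The files gave each probe's sequence, coordinates on 3 replicons and, within genes, a VNG locus tag. Probes were assigned to genes by that tag, in place of the planned rule by gene coordinates, which were not used here. The gene table given for this work carried none of these tags, so the 30 gene lists planned by symbol could not be filled. The strand sequences were rebuilt from the overlapping probes, open reading frames were called with Prodigal 2.6.3, and 2425 of 2622 tags were tied to a frame. Protein families were then read from 140 sequence motifs written before any expression value was tested, but after the sequences were seen. They gave 214 matches, with a protein counted once for each motif it matched, against 6 matches in shuffled proteins. Of these 6, 2 fell to the DNA polymerase B motif, which matched 3 proteins, and 1 to the DNA gyrase motif, which matched 1, so those names were not used and the DNA replication and repair list is less certain. Another 24 motifs were written after values were seen, served only to name genes, and matched 0 shuffled proteins. VNG1701G (L14) and VNG1208G (urocanase), which only these later motifs matched, had first been counted in 2 lists. They were taken out after the list results were seen, and no list gained or lost its call. A family name therefore means that the translated sequence carries the motif. Tags without a match are given by ID alone, at most 2 that rose and 2 that fell per comparison. Gene coordinates are those of the rebuilt frames on the array's replicons. The genome version is not given in the sources used here.

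Probes with another match of at least 50 bases at 90% identity, found with BLAST 2.17.0, were left out. A gene's value was the median over at least 3 unique probes, which left 2131 genes with a median of 9 probes. Another 305 genes with shared probes were kept apart, since their copies cannot be separated. Antisense values were taken for 1961 genes from unnamed probes on the opposite strand.

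The strain difference was fitted in limma with growth phase as a block, leaving 3 residual degrees of freedom. The stage change, stationary minus log averaged over the strains, and the strain by stage interaction came from a fit of 4 group means, with 4 residual degrees of freedom, in which the 2 phases of a stage stood in as replicates. Benjamini-Hochberg adjusted p under 0.05 was the threshold. The labels do not say that the phases came from separate cultures, so the p-values measure only the spread between these samples, and for the stage fit that spread includes differences between the phases of a stage. The 17 lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives. All D2099 arrays lay on 1 slide and all wild type arrays on another, so slide and strain cannot be told apart, and a block for the slide could not be fitted for the strain difference. The stage change within each strain is a value within 1 slide.

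Named genes followed a rule fixed before the data were examined. It took VNG2099C, its 2 neighbours on either side and ura3, then 12 genes per direction for the strain difference and the stage change, and 3 per direction for the interaction. Genes past the threshold came first by size of change and then those with the smallest p, if they moved the same way in all 4 phases or in both strains. Up to 4 members per list with the largest moderated t were added. Alternatives covered background correction, normalization, the authors' values, the gene summary, dim and outlier spots, 10 probes per gene, each dye orientation, the prior, other fits and each sample left out.

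The fits were tested on simulated data with 200 of the 2131 genes changed. For the strain difference 53.3%, 87.5% and 95.6% of genes changed by 1, 2 and 3 log2 units passed the threshold, with 8 false calls. For the stage change the shares were 79.7%, 98.5% and 98.5%, with 16 false calls. These shares hold for the simulated data only. In the strain fit of the measured data the deleted gene VNG2099C differed by -2.87 and did not pass (limma adjusted p = 0.539). A gene that did not pass for the strain difference can therefore still have changed by that much.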

Results

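Transcript levels were compared between the Δura3 parent strain (wild type) and the VNG2099C in-frame deletion strain (D2099) of the halophilic archaeon Halobacterium salinarum, with 4 samples per strain. The optical densities of the wild type samples were 0.3788, 0.7986, 1.2401 and 1.2614 in mid-log, late-log, early stationary and late stationary phase. Those of D2099 were 0.3833, 0.7856, 0.9688 and 1.082. All values are log2 ratios of a sample over the common NRC-1 reference. The 2 dye-exchanged arrays of a sample correlated across genes at r = 0.788 and 0.734 in the wild type log samples, 0.964 and 0.964 in its stationary samples, and 0.792, 0.938, 0.944 and 0.931 in D2099 in the order of the phases. These are correlations across genes, which are not independent replicates.

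VNG2099C, the deleted gene (replicon 1, 1542347 to 1542730, minus strand), carries the motif of the RidA family. It measured -3.76, -3.67, -3.13 and -3.67 in the 4 D2099 samples and -0.31, -0.06, -1.23 and -1.14 in the wild type. The means were -3.56 ± 0.29 (SD, n = 4) in D2099 and -0.68 ± 0.59 (SD, n = 4) in the wild type, a difference of -2.87 ± 0.33 (SE). Its probes were well above background in the sample's channel on 6 to 8 of the 8 D2099 arrays, so the signal there was not background alone. The size of the difference varied with the processing, at -2.55 in the authors' values, -3.03 without offset and -3.35 with the scanner's processed signals. Each of its 4 probes was lower in D2099, by means of -3.23 to -4.10 against -0.58 to -0.75. In the blocked fit its unadjusted p of 0.000253 was the smallest of all genes, and the limma adjusted p was 0.539. Without the phase block it passed (limma adjusted p = 0.029), as it did averaged over the stages (limma adjusted p = 0.00136) and in log phase alone (limma adjusted p = 0.00333). In stationary phase alone it differed by -2.22 and did not pass (limma adjusted p = 0.0616). Over the other settings its limma adjusted p was 0.116 to 0.839. In the wild type it fell from log to stationary phase (limma adjusted p = 0.02). ura3, identified as VNG1673G by its orotidine 5'-phosphate decarboxylase motif (replicon 1, 1246366 to 1247169, plus strand), is absent by design from both strains and present in the reference. It measured -0.88 ± 0.20 (SD, n = 4) in the wild type and -0.61 ± 0.36 (SD, n = 4) in D2099. Its last probe, at 1247065 to 1247124, measured 0.07 in the wild type and -0.23 in D2099, and an internal probe at 1246561 to 1246620 measured -0.21 and 0.24, level with the reference. The probe at 1246813 to 1246872 was not well above background in the sample's channel on any array. Every other probe of ura3 was so on all 8 wild type arrays. With means of -0.88 and -0.61, against -3.56 for VNG2099C in D2099, this gene is a weak check of the labels.

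The genes next to VNG2099C differed less between the strains. VNG2100G, which carries a serine or threonine dehydratase motif, was lowest in the D2099 early stationary sample and lay between -0.09 and 0.36 in the other 7. VNG2097C lay between -0.39 and 0.11 in all samples. VNG2101H was highest in the late stationary samples, at 0.80 in the wild type and 0.92 in D2099. VNG2098H had only 2 unique probes and was not tested. It averaged -0.67 ± 0.57 (SD, n = 4) in the wild type and -0.54 ± 0.78 (SD, n = 4) in D2099.

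**Figure D1:**
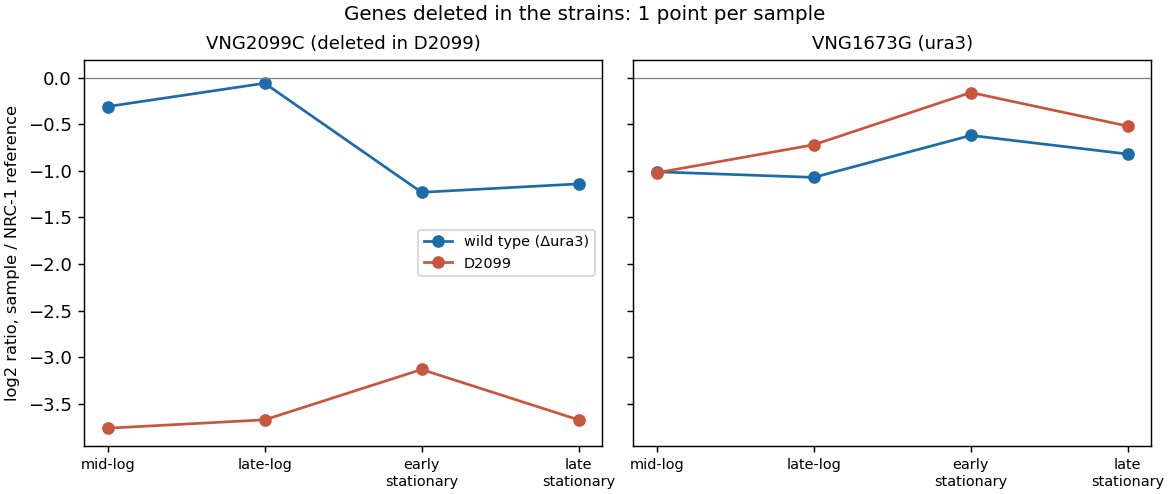
Log2 ratio of sample over NRC-1 reference (vertical axis) for VNG2099C and ura3 in each growth phase, with 1 point per sample and lines joining the samples of a strain. The 4 D2099 samples lie between -3.76 and -3.13 for VNG2099C and the wild type samples between -1.23 and -0.06, while ura3 lies between -1.07 and -0.16 in all 8.

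The design compares the strains over the growth phases. Of the genes higher in D2099 in all 4 phases, the 12 with the smallest p were named. Among these 12, the largest differences lay in the genes of a potassium-uptake ATPase of the Kdp type on replicon 3 (147474 to 152851). KdpA (VNG6176G) was higher by 3.20 ± 0.68 (SE), or 9.18-fold, the P-type ATPase VNG6177G next to it by 2.95 ± 0.72, KdpC (VNG6178G) by 2.66 ± 0.69, and the adjoining universal stress protein gene VNG6179G by 2.51 ± 0.69. KdpA measured 3.57 ± 1.29 (SD, n = 4) in D2099 and 0.38 ± 0.94 (SD, n = 4) in the wild type. Its difference was 2.17, 4.84, 1.25 and 4.54 in mid-log, late-log, early stationary and late stationary phase. Nearby, VNG6175G, with the NAD-binding motif of TrkA proteins that control potassium transport, was higher by 1.21 ± 0.20, and VNG6183C, a DHH family phosphoesterase, by 1.34 ± 0.27. None of these passed the threshold (limma adjusted p from 0.567 to 0.645). The retinal protein gene VNG1467G was higher by 2.52 ± 1.09 on average, with 3.67, 5.84, -0.73 and 1.31 in the order of the phases (limma adjusted p = 0.658).

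**Figure D2:**
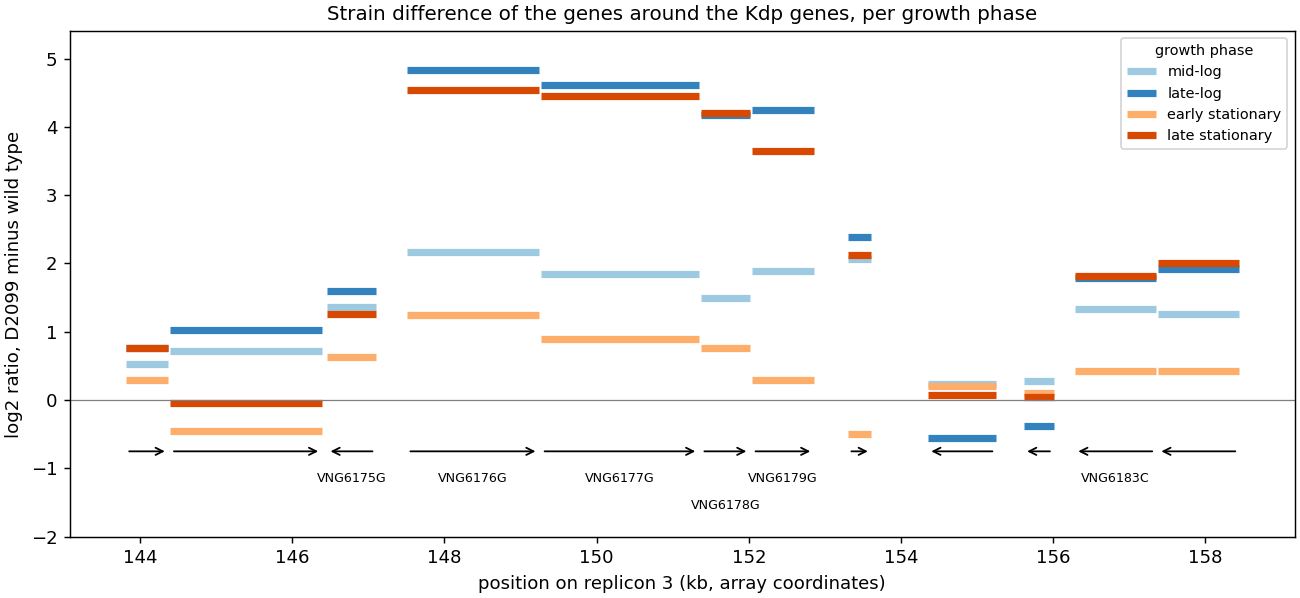
Position on replicon 3 in kb (horizontal axis) against the log2 difference of D2099 minus wild type (vertical axis). Bars are the medians over a gene's probes in each growth phase, with 1 sample per strain, and arrows give the strand. KdpA (VNG6176G) differs by 1.25 to 4.84 over the 4 phases.

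Among genes lower in D2099 in all 4 phases, the FKBP-type peptidyl-prolyl isomerase VNG1294G differed by -1.30 ± 0.21 (SE), the signal peptide peptidase family gene VNG0620G by -1.53 ± 0.30, the DhnA-type aldolase VNG0309C by -1.01 ± 0.17 and VNG0335a, a nucleoside phosphorylase, by -0.80 ± 0.15. Transcription factor S (VNG0426G) differed by -0.71 ± 0.14, the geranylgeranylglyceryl phosphate synthase family gene VNG0252C, of the family that makes archaeal membrane lipids, by -0.84 ± 0.17, and the tRNA amidotransferase subunit VNG0345G by -0.59 ± 0.13. Of the genes with no family match, VNG0146H (-1.69 ± 0.24) and VNG0617H (-1.48 ± 0.30) were lower and VNG6185H (1.07 ± 0.17) and VNG6188H (0.80 ± 0.17) higher. The other 6 genes that the rule names carry no family match. All had limma adjusted p of 0.567 to 0.645. VNG6185H and VNG6188H lie near the Kdp genes. All genes on replicon 3 that were named as higher for their small p lie in a single stretch, from 143760 to 160552. The rest of those named as higher lie on replicon 1. Some other genes within the stretch differed by as little as -0.01 and 0.01 on average.

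Over the 2131 genes, 0 passed the threshold for the strain difference in limma, against 149 at unadjusted p under 0.05. The fit without the phase block, the contrast averaged over stages and the log phases alone each called 1 gene, VNG2099C. The median over all genes was -0.10, and it was -0.20 with median centring and 0.01 in the authors' values. In 394 genes (18.5%, against 12.5% if each sign were a coin flip) the difference had the same sign in all 4 phases. Of them 155 were higher and 239 lower in D2099. A shift common to all genes adds to this count. Differences over 2-fold were counted in each phase without a test. They numbered 69 higher and 18 lower in mid-log, 97 and 224 in late-log, 3 and 251 in early stationary and 64 and 176 in late stationary phase. The D2099 early stationary sample had the lowest median gene ratio of the 8 samples, at -0.43. It also had the lowest median signal in its own channel in each dye, at 692 in green and 266 in red. What this did to its counts was not tested.

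Of the 17 gene lists, 2 passed for the strain difference. The 27 ribosomal protein genes were lower in D2099, with a median of -0.65 and all 27 below 0 (camera adjusted p = 0.00297, and adjusted p = 0.961 with an estimated correlation). Of these genes 0 passed alone, 0 adjusted over the list alone. The S2 gene VNG1143G differed by -0.79 ± 0.31 (SE) and the S13 gene VNG1132G by -0.89 ± 0.40. Without the late-log samples the median was -0.10 (adjusted p = 0.622), and without the mid-log samples -0.57 (adjusted p = 0.154). It was -0.89 without the early stationary samples (adjusted p = 0.000229) and -1.05 without the late stationary ones (adjusted p = 1.17e-08). By phase the median difference was -0.79, -2.22, 0.06 and 0.54. The 19 genes of aerobic respiration and ATP synthesis had a median of -0.40, with 16 below 0 (camera adjusted p = 0.0267, and adjusted p = 0.961 with an estimated correlation). Of these 0 passed, 0 adjusted over the list alone. Cytochrome oxidase subunit II (VNG0665G) differed by -0.54 ± 0.18 and cytochrome b (VNG0583G) by -0.55 ± 0.22. This list's median was -0.20 without the late-log samples (adjusted p = 0.257), -0.22 without the early stationary ones (adjusted p = 0.0656) and -0.39 with the scanner's processed signals (adjusted p = 0.0503). With fry, 0 lists passed. The other 15 lists did not pass with the preset correlation either. Among their members, aconitase (VNG2574G) differed by -1.09 ± 0.27, glutamine synthetase (VNG2093G) by -1.38 ± 0.53, enolase (VNG1142G) by -0.90 ± 0.31, and histidine ammonia-lyase (VNG1212Gm) by 0.56 ± 0.18. Adjusted over the list alone, 1 gene passed in the tricarboxylic acid cycle list, aconitase, and 1 among the P-type ATPases, VNG6177G.

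Between log and stationary phase, the transcripts of ribosomal protein genes fell and those of a retinal protein, a small heat shock protein and a solute transporter rose. All 12 of the largest falls were ribosomal protein genes on replicon 1 between 1259066 and 1270388. L23 (VNG1691G) fell by 3.20 ± 0.44 (SE), or 9.19-fold, with changes of -3.17 ± 0.46 in S17 (VNG1700G) and -2.77 ± 0.42 in S4e (VNG1703G). L24 (VNG1702G), L5 (VNG1705G), L32e (VNG1711G), S5 (VNG1715G), S8 (VNG1707G), L6 (VNG1709G), L14 (VNG1701G), L3 (VNG1689G) and L30 (VNG1716G) fell by amounts between these (limma adjusted p = 0.0159 for all 12). The retinal protein gene VNG1467G, of the family of light-driven pumps and light sensors, rose by 3.34 ± 0.60, or 10.1-fold (limma adjusted p = 0.0184), from a mean of 1.23 ± 2.95 (SD, n = 4) in log to 4.57 ± 0.63 (SD, n = 4) in stationary samples. The call for VNG1467G was lost without the wild type mid-log, late-log or early stationary sample (limma adjusted p = 0.0789, 0.0683 and 0.0568), and over the other settings its limma adjusted p was 0.00218 to 0.0942. The Hsp20 gene VNG1801G rose by 2.64 ± 0.47 (limma adjusted p = 0.0183). These rises were larger in the wild type than in D2099, at 5.57 and 1.11 for VNG1467G and 4.35 and 0.92 for VNG1801G, though the interaction did not pass (limma adjusted p = 0.182 and 0.183). VNG1467G was already at 4.90 in the D2099 late-log sample. The solute-binding protein gene VNG6277G and the ABC permease gene VNG6279G beside it rose by 2.19 ± 0.56 and 2.01 ± 0.52 (limma adjusted p = 0.03 and 0.0306). VNG1463G and VNG6162H, with no family match, rose by 2.88 ± 0.68 and 2.66 ± 0.39. The change of VNG6162H was 5.04 in the wild type (limma adjusted p = 0.0163) and 0.29 in D2099 (limma adjusted p = 0.736), with an interaction of -4.75 that did not pass (limma adjusted p = 0.151), and the other 6 genes that the rule names among the rises carry no family match either.

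In all, 694 of 2131 genes passed for the stage change, 113 higher and 581 lower in stationary phase, with 1012 at unadjusted p under 0.05. In the authors' values 372 rose and 464 fell. The median over all genes was -0.20, against -0.33 with median centring and 0.02 in the authors' values. The count rested on single samples. In limma it was 0 without the wild type mid-log sample (714 at unadjusted p under 0.05), 1 without the wild type late-log sample, 10 without the wild type early stationary sample and 279 without the wild type late stationary sample. It was 334 without the D2099 mid-log sample and 270 without the D2099 early stationary sample. In each of these fits the 694 genes kept their sign. Within the wild type 720 genes passed, 208 higher and 512 lower. Within D2099 0 passed in limma, with 460 at unadjusted p under 0.05, and the difference between the strains is tested by the interaction.

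**Figure D3:**
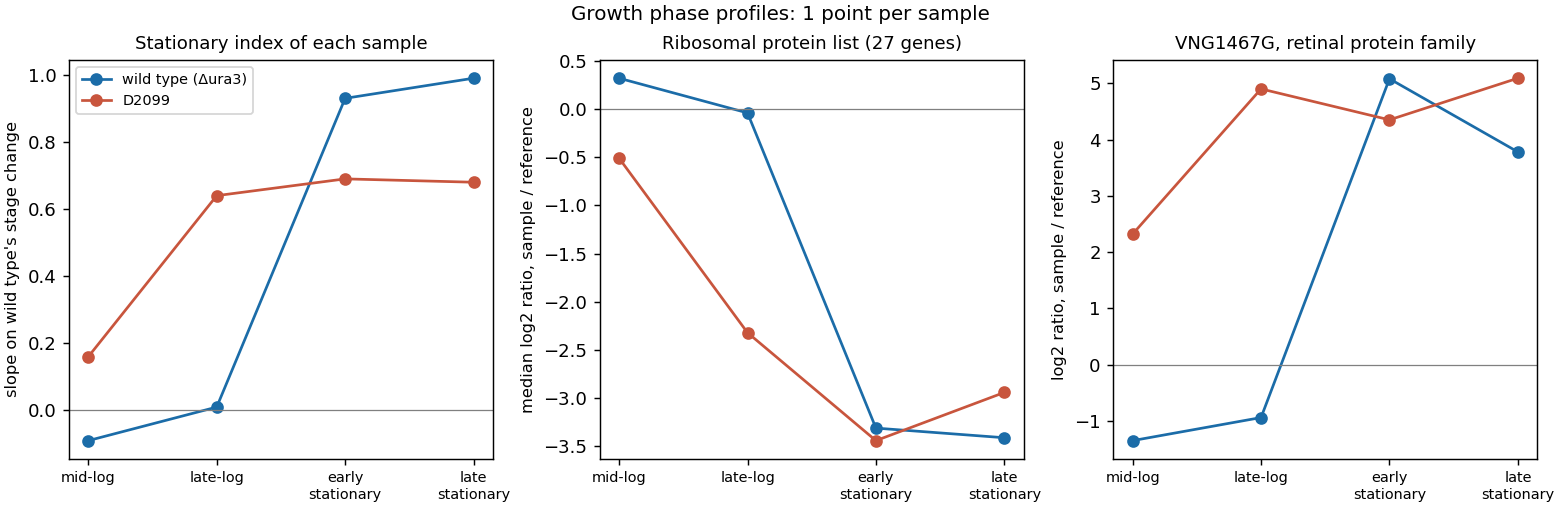
Growth phase (horizontal axes) against the stationary index of each sample, which is the slope of its gene values on the wild type's stage change, the median log2 ratio of the 27 ribosomal protein genes, and the log2 ratio of VNG1467G (vertical axes), with 1 point per sample. The D2099 late-log sample has an index of 0.64, a ribosomal median of -2.32 and a VNG1467G ratio of 4.90, against 0.01, -0.04 and -0.94 in the wild type late-log sample.

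Of the 17 lists, 2 passed for the stage change. All 27 genes of the ribosomal protein list fell, 27 adjusted over the list alone, with a median of -2.54 (camera adjusted p = 9.73e-10, and adjusted p = 0.746 with an estimated correlation). The median was -1.83 to -2.73 over the scalings. The 5 phototrophy genes had a median of 0.69 (camera adjusted p = 0.0422, and adjusted p = 0.746 with an estimated correlation), and 2 rose. Adjusted over the list alone 5 passed, 4 higher and 1 lower. Beside VNG1467G the retinal protein gene VNG0180G rose by 0.69 ± 0.16, while VNG1764G, another of that family, measured -0.68 ± 0.21 (limma adjusted p = 0.0528). The phototrophy call was lost in the authors' values (adjusted p = 0.0948), without the wild type early stationary sample (adjusted p = 0.101), without the wild type late stationary sample (adjusted p = 0.0511) and without the D2099 early stationary sample (adjusted p = 0.0538). With fry, 0 lists passed, with a smallest adjusted p of 0.0518.

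The lists that did not pass still held genes that fell. In translation, 4 of 6 did (4 adjusted over the list alone), with a change of -1.95 ± 0.35 (SE) in elongation factor 2 (VNG2654Gm). In aerobic respiration and ATP synthesis 9 of 19 fell (10 adjusted over the list alone), with changes of -2.11 ± 0.38 and -2.17 ± 0.39 in the ATP synthase subunits VNG2138G and VNG2139G. All 3 glycolysis and gluconeogenesis genes fell (3 adjusted over the list alone), with -2.13 ± 0.35 in enolase (VNG1142G) and -1.55 ± 0.31 in the phosphoenolpyruvate synthase family gene VNG0330G. In the tricarboxylic acid cycle 2 of 5 fell (3 adjusted over the list alone), with -1.61 ± 0.31 in isocitrate dehydrogenase (VNG1873G). In nucleotide synthesis 7 of 8 fell (8 passed adjusted over the list alone, 7 lower and 1 higher), with -2.30 ± 0.46 in aspartate carbamoyltransferase (VNG6309G). Of the ABC transporter ATPases 12 fell and 2 rose of 24 (15 passed in either direction, adjusted over the list alone), and of the ferredoxins 4 of 9 fell (5 adjusted over the list alone). In the cell envelope and division list 3 of 5 fell (4 adjusted over the list alone), with -1.95 ± 0.54 in the S-layer glycoprotein (VNG2679G). Of 14 chaperone and proteolysis genes 2 fell and 1 rose (3 adjusted over the list alone), with -1.13 ± 0.27 in DnaK (VNG0491G). In DNA replication and repair 2 of 7 fell (2 adjusted over the list alone), with -0.80 ± 0.16 in the MCM helicase (VNG2181G). In amino acid use 2 of 11 fell (2 adjusted over the list alone), with -1.47 ± 0.32 and -1.38 ± 0.32 in the glutamate dehydrogenases VNG0628G and VNG1204G. Of the chemotaxis and archaella genes 1 rose and 1 fell of 15 (1 adjusted over the list alone), and of the general transcription factors 1 of 7 fell, VNG0315G with -0.81 ± 0.24 (0 adjusted over the list alone). Of the 3 arginine fermentation genes and the 4 P-type ATPases 0 passed in limma, 0 adjusted over the list alone. Camera ranks a list against the other genes, and its direction differed in sign from the median for chaperones (-0.31), chemotaxis (-0.02) and amino acid use (-0.29) in the stage change, and for nucleotide synthesis (-0.09) and amino acid use (-0.11) in the strain difference. None of these passed.

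The interaction asks whether the stage change differed between the strains. In limma 0 genes passed, with 438 at unadjusted p under 0.05, 7 in the authors' values and 131 after quantile normalization. Without the D2099 mid-log sample 156 passed, and without the wild type early stationary sample 5. The smallest p belonged to VNG6329H, with no family match, whose stage change was 3.69 in the wild type and 0.69 in D2099, a difference of -3.01 ± 0.32 (SE, limma adjusted p = 0.107). VNG1973H, also unmatched, differed by -2.98 ± 0.41. Argininosuccinate lyase (VNG2436G), of arginine synthesis, differed by -2.95 ± 0.38. It measured 1.51 and 1.87 in the wild type stationary samples and -0.38 and -0.15 in its log samples, against 1.34 and 1.88 in the D2099 log samples and 0.39 and 0.86 in the stationary ones. In the other direction VNG0249G differed by 1.96 ± 0.33, VNG0248C by 2.05 ± 0.40 and VNG2099C by 1.32 ± 0.30. None of these passed.

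On the antisense strand 0 of 1961 genes passed for the strain difference in limma, with 370 at unadjusted p under 0.05, and 0 with dim probes left out (394 at unadjusted p under 0.05). The median antisense difference was 0.08. In stationary phase alone 44 antisense values passed, all lower in D2099 (492 at unadjusted p under 0.05), and for the interaction 7 did, all lower (226 at unadjusted p under 0.05). These 2 contrasts were not planned for the antisense strand.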

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

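Every test of an explanation in this part was chosen after the results were seen. A sample was marked where it stood apart from the other 3 of its strain by Dixon's ratio at its 95% critical value. Of 54 sets of 4 values, 6 were marked, and chance marks about 5%, or 2.7 sets. The 4 values of a strain are also its 4 growth phases, so a sample can stand apart through its phase.

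The Kdp genes stood apart in the wild type early stationary sample, where KdpA (VNG6176G) measured 1.77, VNG6177G 1.54 and KdpC (VNG6178G) 1.21. In D2099 VNG2099C was highest in the early stationary sample, at -3.13. The median of the cell envelope and division list was lowest in the wild type early stationary sample, at -1.25. The nucleotide synthesis list had its highest D2099 median in the mid-log sample, at -0.21.

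In 3 lists the stage change differed between the strains by the interaction, at the preset correlation only. The D2099 minus wild type medians were 1.84 for the ribosomal proteins (camera adjusted p = 8.59e-08, higher in 27 of 27 genes), -0.68 for chemotaxis and archaella (adjusted p = 0.0103, lower in 13 of 15) and -1.42 for phototrophy (adjusted p = 0.0242, lower in 5 of 5). With an estimated correlation the adjusted p was 0.727 for each. In limma 0 members of these lists passed over all genes, and adjusted over the list alone 0, 2 and 3 did, in that order. Without the D2099 late-log sample the ribosomal median was 0.90, and without the D2099 mid-log sample 2.79. The phototrophy call was lost without the wild type early stationary sample (adjusted p = 0.0878) and without the D2099 late stationary sample (adjusted p = 0.134).

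The D2099 late-log sample had most of the stationary pattern. Its stationary index was 0.64, against 0.01 in the wild type late-log sample, and between 0.53 and 0.65 over the other scalings, and it correlated across genes at 0.85 with the wild type early stationary sample and 0.31 with the wild type late-log sample. The index is built on the wild type's own stage change, so the separation of the wild type log and stationary samples along it is set by construction. A faulty array would set its 2 arrays apart, and they correlated at 0.938 across genes. To explain the pattern, a swap of labels with a D2099 stationary sample would have to put a sample with a low index among the stationary ones. Over all scalings the lowest of these lay 66.5% of the way from wild type late-log to wild type stationary samples, so a swap would not explain it. The D2099 late-log and stationary samples had like indices (0.64, 0.69 and 0.68), so the index cannot tell whether labels were swapped among them. An earlier turn to the stationary pattern in the knockout may be the source and stays open, as does a culture sampled late, since the sample was at 72.6% of the highest D2099 density and the wild type late-log sample at 63.3% of its own, with 1 sample per phase.

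The Kdp genes were higher in D2099 in all 4 phases, though not past the threshold. Extra copies alone would give a like difference in each phase, and the smallest range over the phases among the 4 genes was 3.44. These genes also changed with the phase in the wild type, so a part from extra copies cannot be excluded. The nearby VNG6175G differed by 1.36, 1.60, 0.63 and 1.26 in the order of the phases, and other neighbouring genes by as little as -0.01 and 0.01 on average. The other genes on replicon 3 named as higher for their small p lie in the same stretch, from 143760 to 160552. Whether that stretch changed as a unit was not tested. A stage sampled in the wild type cannot give the levels of the late-log and late stationary D2099 samples, since the lowest of the 4 genes there measured 4.06 and the highest wild type value was 1.77. The D2099 mid-log sample had a lower index than both D2099 stationary samples under every scaling, at 0.16 against 0.69 and 0.68 in the main setting. It lay 15.9% of the way from wild type late-log to wild type stationary samples, but 55.3% after quantile normalization. Across genes it correlated at 0.555 with the wild type early stationary sample and 0.131 with the wild type mid-log sample. A partial shift of this sample to the stationary pattern therefore stays open. So do a wild type stage for the D2099 early stationary sample, with a median 0.73 above the highest of the wild type, and stages not sampled in the wild type. The 1486 spots neighbouring the 64 probes of these genes differed by a median of 0.01, and the antisense strand of the 4 genes by 0.12 to 0.25. Each dye orientation alone gave 2.31 to 3.31. These values argue against a local fault of a slide for these genes. Any other difference between the slides or cultures could give a change of any size, up to the 4.84 of KdpA in late-log phase. It cannot be told apart from the deletion because every D2099 array lay on 1 slide.

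The ribosomal protein list was lower in D2099 at the preset correlation only (adjusted p = 0.961 with an estimated correlation and 0.775 with fry), with medians of -0.79, -2.22, 0.06 and 0.54 in the order of the phases. In mid-log 27 of 27 genes were also lower, but they come from 1 sample per strain and move together (estimated correlation 0.925), so they are not independent. The list's call was lost without the late-log samples (camera adjusted p = 0.622) and without the mid-log samples (camera adjusted p = 0.154). As measured the level was not lower in every phase, given the 0.54 in late stationary phase. With 1 sample per strain and phase and unlike indices there, a lowering beneath a difference in stage cannot be excluded. The stationary pattern of the D2099 late-log sample may account for the late-log part. The index taken without these genes predicted a difference of -2.18, and -2.22 was measured. What moved that sample stays open. In mid-log phase the index without these genes was also higher in D2099, at 0.16 against -0.09 in the wild type. A difference was predicted for late-log phase only, so whether the same pattern accounts for the mid-log part stays open too. In the stationary samples the index without these genes was lower in D2099, at 0.66 in each, against 0.93 and 0.99 in the wild type. The list's median differences there were 0.06 and 0.54, and no prediction was made for them.

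Other splits of the samples were counted for the results given here, and not for the interaction, whose groups hold 2 samples each. Without strain in the fit, the stage split called 475 genes and the highest of the other 34 splits called 1 (1 of 35 splits). At unadjusted p under 0.05 in limma the stage split gave 846 genes and the highest other split 689. No other split reached the count of the stage split. The samples are growth phases of 2 strains and cannot be exchanged freely, so this count does not exclude chance. Without growth phase the strain split called 1 gene, VNG2099C, and the highest other split, the stage split, called 475, while the other 33 called 0. These 2 of 35 splits are both factors of the design, so this count leaves chance undecided, and the growth stage is the larger structure in these samples. In the fit of 4 group means the stage split called 694 genes and the highest other 298, and on the antisense strand 309 against 137. The 18 splits with 2 samples of each strain on each side are too few for a share under 0.05. For the genes with shared probes the stage split without strain called 35 and the highest other 43, so chance cannot be excluded (2 of 35 splits). The blocked strain split and the antisense strain split called 0 genes each, as did the highest other split, and for the genes with shared probes it called 0 against 2. The 8 splits that part the pairs of a phase are too few for a share under 0.05. For the lists the strain split called 2 and the highest other 6, and these 8 splits are again too few. For the stage change without strain 1 list passed against 8 in the highest other split, so chance cannot be excluded (29 of 35 splits).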

How the results depend on the processing

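Alternatives for single lists and for 3 phosphate genes were added after the data were seen, and the others were planned. The strain difference called 0 genes in every planned setting except 3 with 1 gene each, the fit with no replicate block, the contrast averaged over stages and the log phases alone, all VNG2099C. The growth phase is the pairing of this design, and leaving out each pair gave 0. The stage change called 371 genes after quantile normalization, 335 with at least 10 probes, where only 1020 genes were tested, and 0 in limma between mid-log and late stationary samples alone, with 4 samples (479 at unadjusted p under 0.05). Leaving out 1 sample gave 0 to 812. A lone sample was then assumed to vary like the other groups. The interaction called 7 genes in the authors' values and 131 after quantile normalization, and 0 to 156 with 1 sample left out. The lists past the threshold fell from 2 to 0 with an estimated correlation and to 0 with fry, for the strain difference and for the stage change. Where no construction is named, the cause was not tested. A block for the slide could not be fitted for the strain difference. For the stage change the slide is the strain, and with strain as an additive term 495 genes passed. Of the 694 stage genes, 682 kept their sign in the authors' values and 672 after quantile normalization. Of the named genes' changes only VNG2100G changed sign (0.17 in the log phases alone). Of 902 settings for 42 stage genes 674 gave the same call, 222 lost it and 6 gained it. The filter for dim probes left out 7.7% of probes. A probe lit by the reference RNA alone passed it, so it does not measure how many genes had a dim sample signal.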

Other observations

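No test in this part was planned, and the genes here were chosen after their values were seen. Of the genes read here, 3 with motifs of phosphate uptake or phosphatases rose in stationary phase, and no list of such genes was tested. The PstC-type permease VNG2484G rose by 1.88 (limma adjusted p = 0.0199), the phosphate-binding protein VNG2486G by 1.56 (limma adjusted p = 0.0314) and the alkaline phosphatase VNG6301G by 1.81 (limma adjusted p = 0.0159). VNG2484G measured 0.06, -0.02, 2.67 and 2.00 in the wild type and -0.04, 0.46, 0.84 and 2.49 in D2099, in the order of the phases. VNG6301G measured -0.01, -0.09, 3.04 and 2.69 in the wild type and 0.22, 0.44, 0.51 and 1.56 in D2099, with an interaction of -2.21 that did not pass (limma adjusted p = 0.163). Argininosuccinate synthase (VNG2437G) followed the lyase, at -0.58, -0.22, 1.42 and 1.83 in the wild type and 1.23, 1.87, 0.23 and 0.85 in D2099. The transcription factor B gene VNG0734G measured -0.48, -0.20, 1.22 and 2.40 in the wild type and 0.23, 1.41, 0.66 and 0.90 in D2099.

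Genes with shared probes were not ranked, and 0 of 305 passed for the strain difference in limma (28 at unadjusted p under 0.05) or the stage change (119 at unadjusted p under 0.05), though 35 passed for the stage change without strain in the fit. The archaellin gene VNG0960G, whose probes match other archaellin genes, measured -0.81, -0.21, -0.77 and 0.64 in the wild type and 0.22, 0.32, -1.87 and -0.14 in D2099, in the order of the phases. The gas vesicle gene VNG6029G measured -1.22, -0.34, 0.12 and 2.03 in the wild type and 0.79, -0.57, -2.90 and -0.92 in D2099. The ribosomal RNA features measured 0.15 to 1.06 (16S) and 0.23 to 1.28 (23S) over the samples, highest in the wild type late stationary sample. On the antisense strand 309 genes passed for the stage change, 248 higher and 61 lower in stationary phase, with a median of 0.15 over all 1961. Without strain in the fit these calls were lost, so the count rests on the fit of 4 group means.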
